A study of Mus musculus with 10 samples.

How the data were processed

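Transcripts of a fixed probe panel were counted in place with the Xenium platform in formalin-fixed, paraffin-embedded sections of mouse spinal cord taken at sacral, lumbar and thoracic levels, per the labels' protocols. Sections were 5 micrometres thick, and the series text states 6 slides with 18 samples. The 10 libraries fall into 6 groups. Male RT/saline and male cold have 3 libraries each, of 1 mouse per library. Male 2-DG, female RT/saline, female cold and female 2-DG have 1 library each, pooled from 3 mice whose cells cannot be told apart in the files. RT/saline mice were injected with saline and kept at room temperature for 1.5 h, cold mice were kept at 4 degrees C for 1.5 h, and 2-DG mice were injected with 2-deoxyglucose, an inhibitor of glucose use, at 400 mg/kg and killed after 1.5 h, per the labels' protocols. The labels do not say that cold mice were injected.

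The deposited files hold raw transcript counts per feature and segmented cell, in whole numbers, per the file headers and values. They list 541 features, of which 347 are genes, 27 are negative control probes, 41 are negative control codewords, 125 are unassigned codewords and 1 is a deprecated codeword. Decoding and segmentation settings are not given in the sources used here. Seurat 5.3.0 is named, with no stated role, per the submitters' processing notes. No cell annotation by the authors was used here. The panel description was not analysed here.

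Cells with at least 10 transcripts were kept, which left 3143789 of 3192967 cells, between 97.6% and 99.2% per library. Libraries held 15173701 to 115632242 gene transcripts, with a median of 108 to 135 transcripts per cell before this filter. Work was done with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

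For clustering, 10000 cells were drawn per library, counts were scaled to 100 per cell and log-transformed, and 30 principal components and 20 nearest neighbours entered Leiden clustering at resolution 1. Genes of a fixed list of genes induced by neuronal activity and sex-linked genes were left out of the clustering. Crh is not on that list and stayed in. The other cells took the label of the cluster profile under which their counts were most probable, which returned the cluster label for 88.8% of the clustered cells. The 41412 cells of clusters with Chat among their 10 leading genes, the cholinergic set, were clustered again at resolution 0.5 into 33 clusters. The SPN-like cells, named after the sympathetic preganglionic neuron, were clustered at resolution 0.5 into 18 subclusters. Markers were fixed before the data were examined, as were the tests, the gene lists and the alternative settings except those named below as added. The thresholds of the naming rule were set after clusters had been seen. A name needed at least 3 markers at 2-fold or more in at least 25% of the cells. SPN-like clusters also needed Chat and Slc5a7 in at least 90% and Nos1 in at least 50% of the cells. Slc18a3, a common cholinergic marker, is not among the genes measured. No doublet caller was run. Clusters of the cholinergic set with at least 3 markers of 1 glial or vascular class among their 10 leading genes were called mixed and set aside. The mixed clusters with Nos1 amounted, per 100 SPN-like cells, to 27.3 in male RT/saline, 25.0 in male cold, 30.2 in male 2-DG, 29.8 in female RT/saline, 26.6 in female cold and 27.4 in female 2-DG. A subcluster with oligodendrocyte markers among its leading genes, number 18, was left out of subcluster tests. Subclusters with genes of inhibitory neurons among their leading genes were kept. These include that of Gfra2, with Slc6a5 in 34.0% and Gad1 in 28.6% of its cells, and that of Rprm, with Gad2 in 71.05%. Subclusters are named by their 5 leading genes, of which the text prints 1 to 3.

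Counts were summed per library and cell class, levels are given as CPM (counts scaled to the class total of a library, adjusted by its TMM factor), and the sums were tested with edgeR's quasi-likelihood test (TMM factors, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05). Male cold was compared with male RT/saline in the 6 single-mouse libraries. 2-DG against RT/saline, cold against RT/saline in both sexes, 2-DG against cold, and female against male were contrasts of 1 additive model of treatment and sex over all 10 libraries, each library counted once. Gene lists were tested with fry, once for change in 1 direction and once for change in either direction (mixed), adjusted over the lists. For the share of cells with Fos, each cell was thinned at random to 200 transcripts and shallower cells were left out. Shares were compared between 3 and 3 mice by exact two-sided permutation, whose smallest possible p is 0.1. In simulated counts the male SPN-like test over 327 genes recovered 65% of 1.5-fold and 99.0% of 3-fold changes, the 2-DG test in SPN-like cells over 337 genes 56.1% and 100%, and the male test in all cells over 347 genes 100% of both. In each simulation 98 to 100 genes were changed by each of these folds at once. Far fewer genes passed in the data, where the Benjamini-Hochberg threshold is therefore harder to reach. These rates may thus overstate the recovery in the data. The fry test was also tested on simulated data, and clustering on cells simulated from 8 types.

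Named genes were fixed by rule: every measured gene of the activity list (13 of 46), the 10 called genes with the largest rise and the 10 with the largest fall, and called members of the other lists. In other cell classes these were Fos and the 3 called genes of smallest adjusted p. Alternatives covered DESeq2, library totals in place of TMM, no expression filter, at least 30 transcripts per cell, other definitions of the SPN-like cells (a gate of at least 2 Chat or Slc5a7 transcripts and 1 Nos1 transcript, all cholinergic-like cells, another subsample and seed, activity genes kept in the clustering), male mice of a group summed, other subcluster resolutions, a replicate block, and each library left out in turn. A model term for pooled libraries, a run without the Rxfp1 subclusters (genes and lists) and, for 2-DG in the other classes, the run with male mice summed were added after seeing the data. With the term for pooled libraries, the 2-DG contrasts rest on female 2-DG alone among the 2-DG libraries. Female against male then rests on female 2-DG against male 2-DG, 1 library each. The test of whether 2-DG minus cold differs between subclusters, the 2-DG against cold contrast per subcluster, thinned Fos shares per subcluster (over libraries with at least 10 counted cells) and subcluster shares in male cold and male RT/saline were likewise chosen after seeing the data.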

Results

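The data are transcript counts of a fixed panel of genes in segmented cells of mouse spinal cord sections after 1.5 h at room temperature with saline (RT/saline), in the cold (4 degrees C), or after 2-deoxyglucose (2-DG, 400 mg/kg). The series title places the question in the spinal sympathetic neurons that control lipolysis. Male RT/saline libraries held 16670741, 36264728 and 35538933 gene transcripts in 83912, 172130 and 173341 cells, and male cold libraries held 32407477, 30102405 and 15173701 in 167694, 152358 and 78138 cells. The libraries pooled from 3 mice held 104255888 in 591992 cells for male 2-DG, 109094763 in 598230 cells for female RT/saline, 93928328 in 556964 cells for female cold and 115632242 in 618208 cells for female 2-DG. Clustering gave 12 named cell classes. Oligodendrocyte-like cells made up 27.2% of kept cells, astrocyte-like cells 16.1% and excitatory neuron-like cells 14.4%. The 6960 SPN-like cells, from clusters that carry Chat, Slc5a7 and Nos1, made up 0.221% and came as 963 from male RT/saline, 897 from male cold, 1290 from male 2-DG, 1225 from female RT/saline, 1209 from female cold and 1376 from female 2-DG. Cell by cell, 85.7% of them passed the marker gate of these genes. No marker list for parasympathetic preganglionic neurons of the sacral cord was used, so such cells are not told apart from sympathetic ones. None of the 12 classes differed in share between male cold and male RT/saline past the threshold by exact two-sided permutation (lowest adjusted p 0.3, n = 3 and 3, a design that cannot go below p = 0.1). SPN-like cells were 0.217% ± 0.0528 of the cells in male cold and 0.231% ± 0.0123 in male RT/saline (mean ± SD, n = 3). The SPN-like difference changed sign, to 0.0166 percentage points higher in cold, without male cold replicate 3, and the other classes were not rerun with a library left out.

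Cold raised genes of the immediate early response in the SPN-like cells of males. Fos, a transcription factor gene induced by neuronal activity, stood at 1547 ± 95.3 CPM (counts of the gene scaled to the TMM-adjusted class total of a library) in male cold and 424 ± 172 in male RT/saline (mean ± SD, n = 3 each). Fos rose by 1.97 ± 0.26 (SE) on the log2 scale, Fosb by 2.62 ± 0.41 and Nr4a1, which codes for an orphan nuclear receptor, by 1.86 ± 0.24. Crh, the gene of corticotropin-releasing hormone, rose by 1.85 ± 0.30, and Cd44, a hyaluronan receptor gene, rose by 0.38 ± 0.08. Aldh1a1, which codes for a retinaldehyde dehydrogenase, fell by 0.43. For Fos, Fosb, Nr4a1 and Crh every cold library lay above every RT/saline library. The subclusters described further on were not equally filled. That of Sst, Penk and Rxfp1 held 8.64% of the SPN-like cells in male cold and 2.79% in male RT/saline, and that of Calb2, Ebf3 and Rxfp1 held 7.82% and 2.57%, with every cold library above every RT/saline library in both (exact two-sided permutation p = 0.1, the smallest possible, 0.65 adjusted over subclusters). Without these subclusters the edgeR test called 6 genes, 4 of them also called with them, with Fos at 2.07 (adjusted p = 0.0014) and Crh at 1.94 (0.0045), while Cd44 had 0.12 (0.82) and Aldh1a1 -0.33 (0.056), and Npas4 (1.36, 0.016) and Dusp1 (0.53, 0.036) passed.

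By edgeR's quasi-likelihood test 6 of 321 genes changed, 5 higher and 1 lower, with adjusted p of 0.0090 for Fos and Nr4a1, 0.018 for Fosb and Crh, 0.038 for Aldh1a1 and 0.048 for Cd44. In 71 genes the mice of the groups did not overlap, where chance alone gives 10% of genes. Of the 13 measured activity genes 3 rose and none fell, and 6 rose adjusted over the list alone. The list changed in either direction (fry mixed, adjusted p = 0.036) but did not pass in 1 direction (adjusted p = 0.17). Among the members that did not pass, Npas4 had a log2 fold change of 1.26 (adjusted p = 0.055), Junb 0.67 (0.096), Egr1 0.74 (0.32), Dusp1 0.46 (0.11), Ccn2 0.34 and Bdnf 0.13. Arc had 0.11, Homer1 0.06, Bhlhe40 -0.10 and Gadd45a -0.16. In the neuropeptide list, which also holds Cbln1, Cbln4 and Sncg, 1 of 14 genes, Crh, rose, and 4 rose adjusted over the list alone. The list had an adjusted p of 0.0079 for change in either direction (fry mixed), a median of -0.02 and a mean of 0.35. Without the Rxfp1 subclusters 1 gene, Crh, rose adjusted over the list alone (0.00066 for change in either direction), Sst went from 1.21 to 0.35, Penk from 1.07 to 0.06 and Tac1 from 1.02 to 0.56. Sst and Penk lead a subcluster that was removed, so more such cells and more transcripts per cell cannot be told apart. Mural cell markers also changed as a list in either direction (adjusted p = 0.036), with a median log2 fold change of 0.19 over 8 members, none of them past the threshold on its own, but not without the Rxfp1 subclusters (0.78). Without male RT/saline replicate 2 the edgeR test called 0 genes and Fos had 1.87 with adjusted p = 0.072, the count was 13 without male RT/saline replicate 1, 3 without replicate 3 and 2 without male cold replicate 2, and DESeq2 called 16. Over the wider marker gate 0 genes passed, with Fos at 0.79 (adjusted p = 0.28), and over all cholinergic-like cells 0 passed, with Fos at 0.36 (adjusted p = 0.38).

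**Figure D1:**
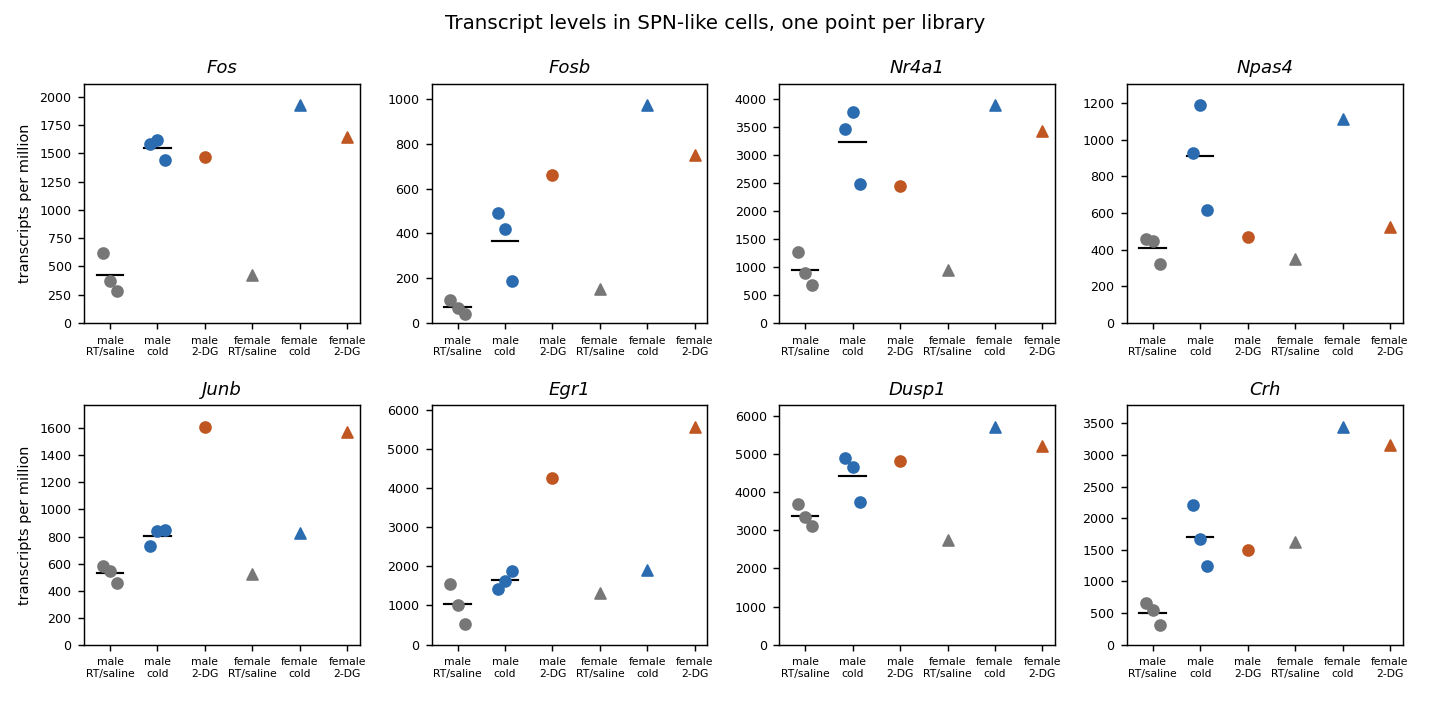
CPM in SPN-like cells (y axis, counts scaled to the TMM-adjusted class total) for 8 genes, with 1 point per library and a line at the mean of the 3 male mice of a group. Circles are males and triangles are females. Fos lay between 1439 and 1621 in the male cold libraries and between 287 and 617 in the male RT/saline libraries.

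After thinning each cell to 200 transcripts, 19.0% ± 2.23 of SPN-like cells in male cold and 8.06% ± 3.84 in male RT/saline held a Fos transcript (mean ± SD, n = 3). The exact two-sided permutation p was 0.1, the smallest that this design allows. Thinning left out 36 cells of male cold and 43 of male RT/saline, and without thinning the shares were 31.3% and 19.6%. Over the wider marker gate the thinned shares were 12.6% ± 2.79 in male cold and 9.42% ± 0.945 in male RT/saline (exact two-sided permutation p = 0.2). In oligodendrocyte-like cells, taken as background, the thinned shares were 6.52% and 6.98%. Median depth of the counted cells lay between 651 and 804 transcripts in SPN-like and between 248 and 252 in oligodendrocyte-like cells. Of about 228950 oligodendrocyte-like cells in both male groups, 97159 and 106786 were left out. Without thinning their shares were 2.74% in male cold and 3.01% in male RT/saline. Thinned to 400 transcripts they were 16.6% and 19.1%, against 27.8% and 13.1% in SPN-like cells. The background thus depends on the depth cut and is no fixed floor for the SPN-like shares.

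Over all cells, endothelial markers were among the genes that changed in cold males, and Fos did not pass. Dusp1, a phosphatase that switches off MAP kinases, rose by 0.42 ± 0.05 on the log2 scale, as did Nostrin (0.42), Pglyrp1 (0.42), Th (0.38), the enzyme gene of catecholamine synthesis, and Sla (0.35). Cldn5, which codes for a tight junction protein of endothelial cells, fell by 0.48, Kdr, a receptor gene for vascular endothelial growth factor, fell by 0.30, and Pecam1 and Ly6a fell by 0.17 and 0.16. Arc fell by 0.51. Fos had a log2 fold change of -0.08 (adjusted p = 0.73). In total 10 of the panel's genes changed by the edgeR test, 5 in each direction, with 82 genes whose mice did not overlap. Of 17 endothelial markers 2 rose and 4 fell, with an adjusted p of 0.00099 for change in either direction. Of the activity genes Dusp1 rose and Arc fell, 11 did not pass, among them Bhlhe40 (-0.13, adjusted p = 0.051), Gadd45a (0.15), Junb (-0.21), Egr1 (-0.35), Nr4a1 (0.17), Ccn2 (0.18), Fosb (-0.11), Bdnf (-0.03), Homer1 (-0.02) and Npas4 (0.00210). DESeq2 called 30 genes. The edgeR test called 3 without male cold replicate 2 and 6 without male cold replicate 3.

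Among the other 11 classes, endothelial-like cells of cold males had more Dusp1 (log2 fold change 1.53 ± 0.08), Nr4a1 (1.38 ± 0.11) and Pglyrp1 (0.45), each past the threshold. Dusp1 also rose in microglia- or macrophage-like cells (1.38 ± 0.12) and mural-like cells (0.37). Gadd45a rose by 0.44 in oligodendrocyte-like cells, in which 16 genes changed, while Arc fell by 0.56 there, by 0.61 in microglia- or macrophage-like cells and by 0.66 in inhibitory neuron-like cells. Junb fell by 0.42 in inhibitory neuron-like cells. The edgeR tests made 54 calls over the classes, 28 higher and 26 lower, with 531 at an unadjusted p under 0.05 among 3791 tests. Fos did not pass in any of the 11 classes. Its log2 fold change was highest in endothelial-like cells at 0.58 (adjusted p = 0.29), and it was -0.04 in skeletal motor neuron-like cells. In excitatory neuron-like, skeletal motor neuron-like and meningeal or fibroblast-like cells the edgeR test called 0 genes, with 57, 48 and 20 at an unadjusted p under 0.05, and DESeq2 was not run on these classes.

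After 2-DG, SPN-like cells held more transcripts of several immediate early genes. Fosb rose by 2.89 ± 0.36 (SE) on the log2 scale, Egr1, a zinc finger transcription factor gene, by 2.10 ± 0.30, Fos by 1.88 ± 0.23, Junb by 1.61 ± 0.13 and Nr4a1 by 1.59 ± 0.23. Homer1, which codes for a postsynaptic scaffold protein, rose by 0.40 ± 0.09, and Crh rose by 1.36 ± 0.29. Fos stood at 1464 CPM in male 2-DG (exact 95% Poisson interval 1388 to 1544) and at 1650 in female 2-DG (1571 to 1731), against 424 ± 172 in male RT/saline (SD, n = 3) and 422 in female RT/saline (380 to 467). The Poisson intervals here and below cover counting error only, not the spread between mice. For these 7 genes the 2-DG library lay above RT/saline of its own sex in both sexes.

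By edgeR's quasi-likelihood test over 10 libraries (2 of 2-DG, 4 of RT/saline, 4 of cold) 7 of 341 genes changed, all higher, with adjusted p of 6.9e-05 for Junb, 0.0014 for Fos and Fosb, 0.0032 for Egr1, 0.0033 for Nr4a1 and 0.042 for Crh and Homer1. Of the 13 activity genes 6 rose and none fell, and 8 rose adjusted over the list alone. The list rose on balance (fry, adjusted p = 0.0036). Among the members that did not pass, Dusp1 had a log2 fold change of 0.64 (adjusted p = 0.094), Arc 0.49 (0.14), Npas4 0.35 (0.95), Bdnf 0.15, Ccn2 0.07, Gadd45a 0.06 and Bhlhe40 -0.08. Of 15 genes of the neuropeptide list 1 rose, with an adjusted p of 0.43 for change in either direction (fry mixed). Over the marker gate 1 gene passed, with Fos at 0.70 (adjusted p = 0.23), and over all cholinergic-like cells 1 gene passed, with Fos at 0.03 (adjusted p = 0.999), where the alternatives for Fos spanned adjusted p from 1.8e-11 to 0.999.

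Over all cells, 2-DG went with changes in endothelial and microglial genes. Nostrin, which codes for a partner of endothelial nitric oxide synthase, rose by 0.49 ± 0.07 (SE) on the log2 scale, Gadd45a, a stress response gene, by 0.29 and Pglyrp1 by 0.23. Cldn5 fell by 0.55, Siglech, a microglial lectin gene, fell by 0.38, Cd300c2 fell by 0.34 and Trem2, a microglial receptor gene, fell by 0.27. Junb fell by 0.33 and Bhlhe40 fell by 0.22. Fos had a log2 fold change of -0.46 (adjusted p = 0.10). The edgeR test called 9 genes, 3 higher and 6 lower. Of 17 endothelial markers 2 rose and 1 fell (fry mixed, adjusted p = 2.2e-05), of 10 microglial markers 2 fell (0.0045) and of 13 activity genes 1 rose and 2 fell (0.0028). Activity genes that did not pass included Arc (-0.45, adjusted p = 0.053) and Dusp1 (0.37, 0.079). The count was 0 with the male mice of a group summed, 22 with a model term for pooled libraries, 27 by DESeq2, 3 without male RT/saline replicate 2, 4 without male RT/saline replicate 3 or male cold replicate 2, 5 without female cold, 22 without male 2-DG and 64 without female 2-DG.

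Among the other 11 classes, genes differed after 2-DG in microglia- or macrophage-like cells (16), endothelial-like cells (12) and mural-like cells (1). Dusp1 rose by 1.24 ± 0.16 (SE) in microglia- or macrophage-like cells, where Eya4 fell by 0.53 and Siglech fell by 0.46. In endothelial-like cells Pde7b, a phosphodiesterase gene, rose by 0.66 ± 0.06, Nostrin by 0.61 and Sla by 0.68. Bhlhe40 fell by 0.52 in mural-like cells. The edgeR tests made 29 calls, 18 higher and 11 lower, with 512 at an unadjusted p under 0.05 among 3812 tests. Both 2-DG libraries were pooled, and with a model term for pooled libraries there were 176 calls, 34 higher and 142 lower, 13 of them among the 29. That term leaves the contrast to female 2-DG alone among the 2-DG libraries. Under it the called genes named here kept their direction, with Dusp1 at 1.59, Eya4 at -0.48, Siglech at -0.36, Pde7b at 0.66, Nostrin at 0.78, Sla at 0.74 and Bhlhe40 at -0.57. With the male mice of a group summed, which leaves fewer libraries, 1 call remained. The number of calls thus depends on the model, and pooling as the cause was not shown. Fos did not pass in any of the 11 classes. Its log2 fold change was -0.76 in inhibitory neuron-like cells (adjusted p = 0.073), -0.68 in excitatory neuron-like cells (0.087) and -0.59 in skeletal motor neuron-like cells (0.19).

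With females added, cold raised in SPN-like cells Fosb (2.58 ± 0.34 (SE) on the log2 scale), Fos (2.00 ± 0.20), Nr4a1 (1.87 ± 0.20), Crh (1.59 ± 0.25), Npas4, a neuronal activity-dependent transcription factor gene (1.34 ± 0.20), and Junb (0.63 ± 0.11). Aldh1a1 fell by 0.40. In the female cold library Fos stood at 1925 CPM (exact 95% Poisson interval 1830 to 2024), against 422 in female RT/saline. The change from RT/saline to cold was 1.87 in males and 2.19 in females for Fos, 1.15 and 1.67 for Npas4 and 0.39 and 1.06 for Dusp1, given as values with no test because each female group is 1 library. By the edgeR test over 10 libraries 7 of 341 genes changed, with adjusted p of 0.00054 for Fos, 0.0059 for Npas4, 0.012 for Junb and 0.033 for Aldh1a1. Of the 13 activity genes 5 rose and none fell (fry, adjusted p = 0.014 on balance), and Dusp1 had 0.57 with adjusted p = 0.054. Without the female cold library the count was 12. Over all cells 11 genes changed, 4 higher and 7 lower, among them Dusp1 (0.45), Pglyrp1 (0.37), Arc (-0.53), Cldn5 (-0.48), Prox1 (-0.23) and Pou3f1 (-0.20). That count was 7 without male RT/saline replicate 2 or male cold replicate 3 and 0 with the male mice of a group summed.

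Set directly against cold, 2-DG gave more Junb in SPN-like cells, by 0.98 ± 0.13 (SE) on the log2 scale, with both 2-DG libraries (1572 and 1609 CPM) above all 4 cold libraries (731 to 846). Junb was the 1 gene of 341 past the threshold (edgeR, adjusted p = 0.0061). Egr1 had 1.45 (adjusted p = 0.12), Npas4 -0.98 (0.22), Homer1 0.35 (0.22), Arc 0.45 (0.29) and Fos -0.12 (0.93), none past the threshold. As a list the activity genes differed in either direction (fry mixed, adjusted p = 3.0e-05), with 4 higher and 1 lower adjusted over the list alone. The count was 0 without female cold, without male 2-DG or with a model term for pooled libraries, 3 without female 2-DG, 2 without male RT/saline replicate 1 or 3, and 4 by DESeq2. Over all cells 1 gene differed, Gm2115 (0.22, adjusted p = 0.031).

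**Figure D2:**
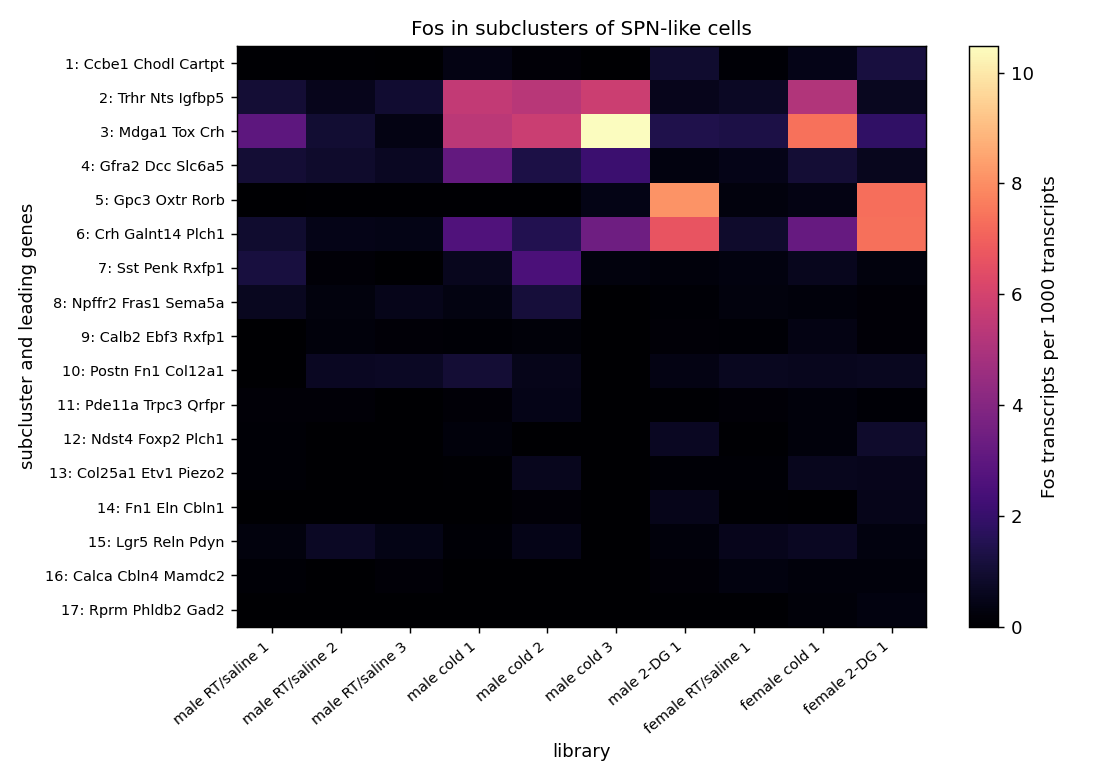
Fos transcripts per 1000 transcripts (colour) in 17 subclusters of SPN-like cells (y axis, with leading genes) in each of the 10 libraries (x axis). In the Trhr subcluster the male cold libraries lay between 5.31 and 5.81 and the 2-DG libraries at 0.542 and 0.641.

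The SPN-like cells fell into subclusters, between which the change of Fos from cold to 2-DG differed. In the subcluster led by Trhr, the thyrotropin-releasing hormone receptor gene, and Nts, the neurotensin gene, Fos rose in male cold by 2.76 ± 0.24 (SE) on the log2 scale. In the subcluster led by Gpc3 and Oxtr, the oxytocin receptor gene, Fos rose after 2-DG by 5.88 ± 0.46. Thinned to 200 transcripts, 69.6% ± 4.75 (SD, 4 libraries) of the Trhr cells held Fos after cold, 15.5% ± 2.56 (4 libraries) in RT/saline and 9.55% ± 2.63 (2 libraries) after 2-DG. In the Gpc3 cells, over libraries with at least 10 counted cells, the shares were 60.8% ± 6.60 (2 libraries) after 2-DG, 3.28% ± 2.88 (3 libraries) after cold and 1.96% ± 3.40 (3 libraries) in RT/saline. Without thinning, the Trhr shares were 87.0%, 37.2% and 29.6% and the Gpc3 shares 79.4%, 8.95% and 8.46%, in the same orders.

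In male cold Fos rose in 5 of 16 subclusters tested (edgeR, adjusted over the subclusters): that of Trhr (adjusted p = 1.5e-05), that of Crh and Galnt14 (2.12, 0.00040), that of Mdga1 and Tox (2.39, 0.015), that of Ccbe1 and Chodl (2.45, 0.049) and that of Gfra2 and Dcc (1.33, 0.0496). Slc6a5 and Gad1, genes of inhibitory neurons, are also among the leading genes of the Gfra2 subcluster. Its cells had a median of 0.66 times the SPN-like depth of their own library. Over both sexes the thinned shares of cells with Fos after cold and in RT/saline were 23.5% ± 11.1 and 13.2% ± 4.93 in the Crh subcluster (SD, 4 and 4 libraries, overlapping, with male cold replicate 3 at 8.33%, 1 of 12 cells, below the lowest RT/saline library at 8.70%), 69.1% ± 11.1 and 23.4% ± 18.0 in that of Mdga1, and 7.28% ± 2.45 and 0.958% ± 1.16 in that of Ccbe1 (3 and 4 libraries each). In the Gfra2 subcluster the thinned shares also overlapped and did not show the rise, at 9.71% to 35.7% in 3 cold libraries and 12.9% to 38.5% in 4 RT/saline libraries, with females at 9.71% in cold and 12.9% in RT/saline. Without thinning, the shares were 44.3% and 25.8% for Crh, 97.5% and 48.0% for Mdga1, 14.4% and 5.02% for Ccbe1, and 39.2% and 29.5% for Gfra2. Within the Trhr cells Nr4a1 rose by 2.71, Npas4 by 2.06, Fosb by 4.16 and Dusp1 by 0.98. Within the Mdga1 cells Nr4a1 rose by 2.52, Crh by 2.67, Npas4 by 2.20 and Dusp1 by 1.38. In the subcluster of Pde11a, Vip, the gene of vasoactive intestinal peptide, fell by 2.34 and Postn rose by 2.63, calls that rest on 10, 14 and 2 cold cells and 7, 10 and 21 RT/saline cells. In the Fn1 subcluster Gad2, an enzyme gene of GABA synthesis, also passed (adjusted p = 0.032), with 18, 63 and 32 transcripts in 19, 13 and 5 cold cells and 0, 2 and 1 in 4, 6 and 18 RT/saline cells, a ratio of summed counts per total of 37.9 (exact 95% Poisson interval 12.6 to 186). After 2-DG Fos rose in 5 of 17 subclusters: that of Gpc3 (adjusted p = 2.4e-07), that of Crh (3.46, 8.8e-08), that of Ccbe1 (3.93, 1.1e-05), that of Ndst4 (4.20, 0.00019) and that of Fn1 and Eln (3.55, 0.0018). The subclusters of Crh and of Ccbe1 thus passed in male cold and after 2-DG. After 2-DG the thinned shares were 59.8% ± 15.7 in the Crh subcluster, 13.0% ± 0.274 in that of Ccbe1, 15.8% ± 4.03 in that of Ndst4 and 8.85% ± 1.63 in that of Fn1 (SD, 2 libraries each). In RT/saline they were 0.446% ± 0.893 for Ndst4 (4 libraries) and 0 of 67 cells for Fn1 (2 libraries), which allows up to 4.48% by counting error alone and only at the thinned depth. Without thinning, they were 74.6%, 30.2%, 32.5% and 19.7% after 2-DG, and 2.56% for Ndst4 and 4.08% for Fn1 in RT/saline. In the Gpc3 cells 14 genes rose, with Egr1 at 5.59, Fosb at 6.60, Nr4a1 at 5.27, Junb at 3.92, Cartpt, the gene of a neuropeptide precursor, at 1.07, Adcyap1, the gene of the peptide PACAP, at 0.58 and Nos1 at 0.37. In the Crh cells Egr1 rose by 4.80, Junb by 4.19 and Crh by 2.21.

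Set directly against cold, 2-DG gave less Fos in the subclusters of Trhr (fell by 3.26), Mdga1 (fell by 2.09), Gfra2 (fell by 1.79) and Npffr2 (fell by 1.79), and more Fos in those of Gpc3 (5.26), Fn1 (3.47), Ndst4 (2.30), Ccbe1 (1.69) and Crh (1.41), 9 of 17 past the threshold. The thinned shares of libraries with at least 10 counted cells overlapped in 2 of these, that of Gfra2 (9.71% to 35.7% in 3 cold libraries, 6.98% and 11.1% after 2-DG) and that of Npffr2 (0%, 3.85% and 23.1% in cold, the last 3 of 13 cells, and 1.16% and 1.28% after 2-DG). For Ndst4 only female cold (2.33%) held at least 10 counted cells among the cold libraries, and 1 of 5 cells in male cold replicate 1 held Fos, a higher share than the 12.9% and 18.6% after 2-DG. The change from cold to 2-DG differed between subclusters for 9 of 299 genes by an edgeR interaction test over 10 libraries, 8 of them activity genes (Fos adjusted p = 8.6e-18) and the other Crh (0.0017). Crh was also used to form the subclusters, so its call is not independent of them. A term for pooled libraries leaves the change from cold to 2-DG in each subcluster to female 2-DG alone among the 2-DG libraries. With a model term for pooled libraries the Trhr (fell by 2.999), Gpc3 (4.36) and Crh (1.22) subclusters passed and 6 of the 9 did not, those of Mdga1 (-1.96, adjusted p = 0.055), Fn1 (3.08, 0.10), Ndst4 (2.12, 0.12), Ccbe1 (1.29, 0.14), Gfra2 (-0.89, 0.36) and Npffr2 (-0.96, 0.63). For male cold alone the interaction test called 0 of 260 genes, with 19 at an unadjusted p under 0.05 and Fos at adjusted p = 0.60, so a cold response confined to some subclusters was not shown in males, and DESeq2 was not run on it.

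**Figure D3:**
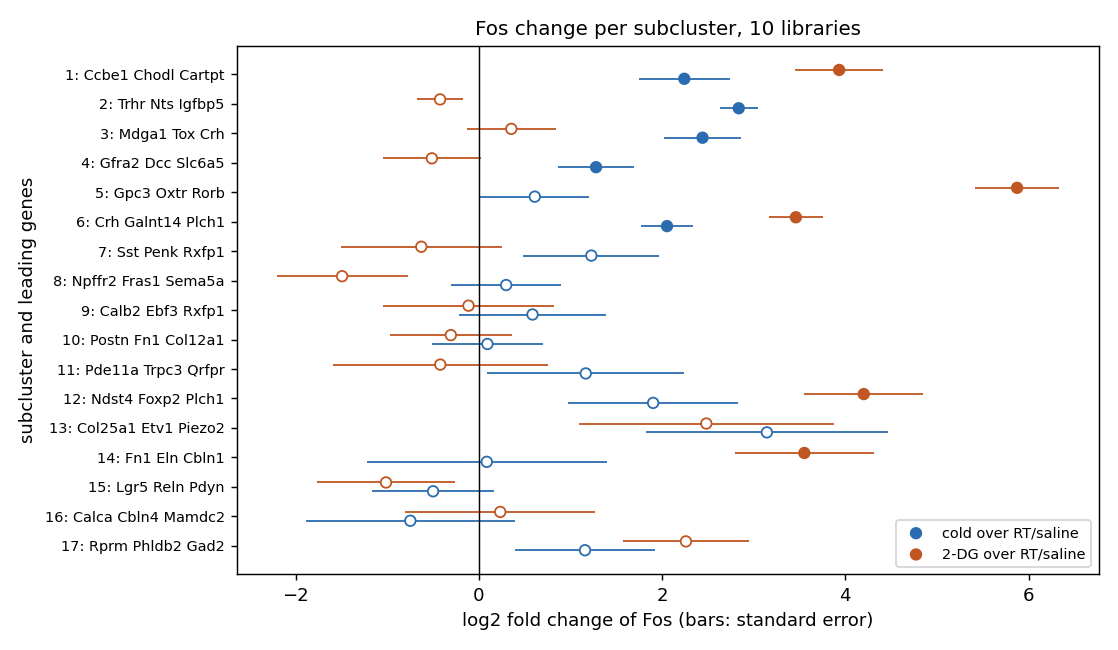
Log2 fold change of Fos over RT/saline (x axis) in 17 subclusters (y axis) after cold and after 2-DG, over 10 libraries; bars are standard errors and filled points have an adjusted p under 0.05. After 2-DG the Gpc3 subcluster lies at 5.88 and the Trhr subcluster at -0.42.

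Female SPN-like cells had less Col25a1, a collagen gene, and less Etv1, a transcription factor gene, than male ones. Col25a1 fell by 1.91 ± 0.14 (SE) on the log2 scale from male to female and Etv1 fell by 1.46 ± 0.13, and Piezo2, the gene of a mechanically activated channel, fell by 0.80. All 3 female libraries lay below all 7 male libraries for Col25a1 (471 to 591 against 1594 to 2439 CPM). These genes lead 1 subcluster, whose size is not compared because they define it. By the edgeR test 41 of 341 genes differed, 20 higher and 21 lower in females, among them Npy2r (-0.72), Rprm (-0.71), Tacr1 (-0.34) and Chat (-0.16), and Crh (1.27) and Sst, the somatostatin gene (1.31). Endothelial markers were higher as a list in female SPN-like cells (fry, adjusted p = 0.0094), with 3 of 17 past the threshold. All 3 female libraries and 1 of 7 male libraries were pooled, and with a model term for pooled libraries most of the 41 genes no longer passed. That term leaves the sex difference to female 2-DG against male 2-DG, 1 library each, with Col25a1 at -2.02 and Etv1 at -1.58. Without that term the count of genes was 3 with male mice of a group summed, 2 without female RT/saline, 17 without female cold, 23 without male 2-DG and 26 without female 2-DG.

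Glp2r, Lhfpl2 and Cdh23 were higher in females by 3.89, 2.85 and 1.56, and were also high in the pooled male 2-DG library. Over all cells Glp2r stood at 357 ± 41.6 CPM in the single-mouse male libraries (SD, n = 6), 5984 in male 2-DG, 7309 in female 2-DG, 10350 in female RT/saline and 12700 in female cold. Over all cells 134 genes differed between females and males, 80 higher and 54 lower. This count was not rerun with a term for pooled libraries or under the other alternatives. Meningeal or fibroblast-like cells made up 12.5%, 11.75% and 10.08% in female RT/saline, cold and 2-DG and 11.79% in male 2-DG. Their means were 7.79% in male cold and 6.92% in male RT/saline. Sex, pooling and cell make-up thus cannot be told apart in this count.

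**Figure D4:**
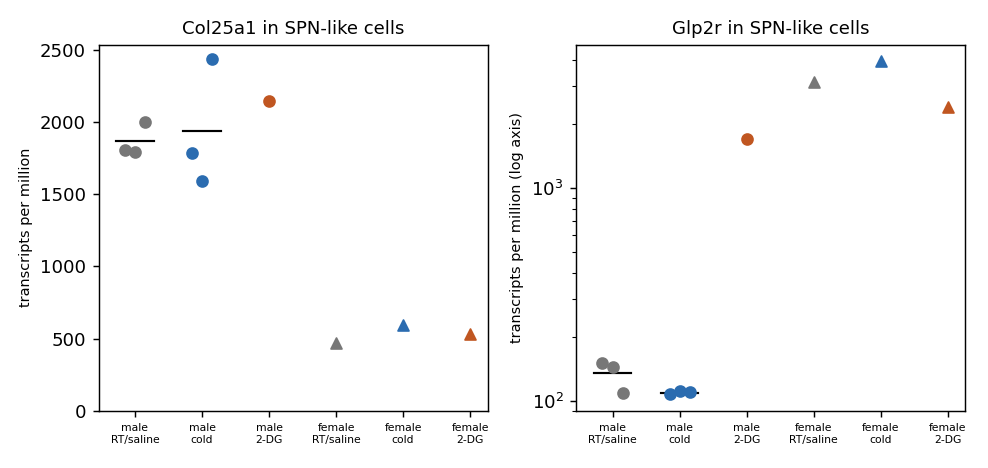
Col25a1 in SPN-like cells in CPM and Glp2r in SPN-like cells in CPM on a log axis (y axes), 1 point per library with a line at the mean of the 3 male mice of a group; circles are males and triangles are females. Col25a1 lay between 1594 and 2439 in the male libraries and between 471 and 591 in the female libraries.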

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

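The test of whether the change from cold to 2-DG differs between subclusters, every test of an explanation here except that without the Col25a1 subcluster, and the grouping of subclusters in these tests were chosen after the results had been seen.

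The change of Fos from cold to 2-DG differed between subclusters of SPN-like cells, with an adjusted p of 8.6e-18 for the interaction (edgeR, 10 libraries), while in the Crh and Ccbe1 subclusters Fos rose both in male cold and after 2-DG. Transcripts from a whole other cell class would raise Fos in that class as well, but its highest log2 fold change in the other named classes under either treatment was 0.58. Sums over whole classes cannot exclude transcripts from the few cells beside SPN-like cells, and the mixed and unnamed clusters were not tested. After thinning to equal depth, the smaller gap between the libraries of both treatments in the Trhr and Gpc3 subclusters was 50.7 percentage points of cells with Fos over libraries with at least 10 counted cells. It was 45.0 with male cold replicate 3, which held 9 Gpc3 cells, and this argues against depth for both. The gaps were 27.7 in that of Mdga1, 15.4 in Crh, 4.47 in Fn1 and 3.53 in Ccbe1, which also go against depth, less so where the gap is small. These subclusters were grouped after their gaps had been seen. Male cold replicate 3, with 5 cells each in those of Mdga1, Fn1 and Ccbe1, did not enter. Depth stays open for those of Gfra2 and Npffr2, whose libraries overlapped (smallest gap -1.40), and of Ndst4, with 1 such cold library. With a term for pooled libraries, the change rests on female 2-DG alone among the 2-DG libraries. Its smaller size in the Trhr and Gpc3 subclusters was then 2.999 on the log2 scale, and 1.22 in that of Crh. This argues against pooling as the whole cause for these 3, on 1 2-DG library. The other 6 kept their sign but no longer passed, so pooling is neither shown nor excluded there. Their sizes were 1.29 to 3.08 for Mdga1, Fn1, Ndst4 and Ccbe1, 0.96 for Npffr2 and 0.89 for Gfra2. A response of partly different preganglionic neurons to cold and to 2-DG may account for the pattern in the Trhr and Gpc3 subclusters, as a hypothesis found and tested on the same data.

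Negative control probe counts were above the highest male RT/saline library (548 CPM, scaled to all counts of a library) in the pooled libraries, with 1340 CPM in female RT/saline, 1369 in female cold, 641 in male 2-DG and 817 in female 2-DG. Of the single-mouse male cold libraries, replicates 1 and 2 also lay above it (594 and 579) and replicate 3 below it (489).

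Col25a1 and Etv1 were lower in SPN-like cells of females. With a term for pooled libraries, the less negative of both log2 fold changes was -1.58, which argues against pooling as the whole cause. Without the subcluster that Col25a1 leads its log2 fold change was -0.17, but the gene defines that subcluster, so fewer such cells and fewer transcripts per cell cannot be told apart. The subcluster's share varied 1.80-fold among male libraries, and sections from different spinal levels cannot be told apart from sex because no level is given per section. Sex itself stays open and untested.

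Glp2r, Lhfpl2 and Cdh23 were higher in the libraries pooled from 3 mice. In the male 2-DG library Glp2r was 16.8 times and Lhfpl2 4.84 times the mean of the single-mouse male libraries, which argues against sex alone for these genes and rests on 1 library. Cdh23 was 1.86 times that mean (5941 CPM, against 4366 in the highest single-mouse male library), which leaves sex open for it. Each of the 3 genes was at least 2 times higher in the pooled libraries in 12 of 12 named classes, so probe background that differs between library sets is a candidate explanation. No biological explanation other than sex was tested.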

How the results depend on the processing

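The term for pooled libraries, the run without the Rxfp1 subclusters and the 2 alternatives for 2-DG in the other classes were chosen after seeing the data. Of 201 alternatives, 154 kept their direction and side of the threshold, or a count within 1.5-fold, 41 moved, 5 weakened, 0 strengthened and 1 reversed. The cause was not tested for any of these unless stated. In SPN-like cells male cold gave 6 genes, 16 by DESeq2, 0 over the marker gate and 0 over all cholinergic-like cells, with 50 at an unadjusted p under 0.05 in the edgeR test. Without the Rxfp1 subclusters it gave 6 genes, 4 of them also called with all cells of the class, and Cd44 went from 0.38 to 0.12. Its Fos log2 fold change was 0.79 over the gate (adjusted p = 0.28) and 0.36 over cholinergic-like cells (0.38), where adjusted p spanned 4.9e-11 to 0.376 over the alternatives. Both definitions hold many more cells than the SPN-like class. Leaving out 1 library gave 0 to 13 genes, 13 without male RT/saline replicate 1, 0 without replicate 2 (Fos 1.87, adjusted p = 0.072), 3 without replicate 3 and 2 without male cold replicate 2, and Fos spanned 1.73 to 2.30. Over all cells male cold gave 10 genes, 30 by DESeq2 and 3 to 12 with 1 library left out, 3 without male cold replicate 2 and 6 without replicate 3. For 2-DG in SPN-like cells 7 genes became 1 over the marker gate and 1 over all cholinergic-like cells, with Fos at 0.70 (adjusted p = 0.23) and 0.034 (0.999), and 5 to 8 with 1 library left out. For 2-DG over all cells 9 genes became 27 by DESeq2, 0 with male mice of a group summed, 22 with the term for pooled libraries, and 3 to 64 with 1 library left out, 3 without male RT/saline replicate 2, 4 without replicate 3, 4 without male cold replicate 2, 5 without female cold, 22 without male 2-DG and 64 without female 2-DG. For 2-DG in the other 11 classes 29 calls became 176 with the term for pooled libraries, 13 of them shared, and 1 with male mice of a group summed. Cold in both sexes gave 7 genes in SPN-like cells, 5 to 12 with 1 library left out (12 without female cold), and 11 over all cells, 0 with male mice summed and 7 to 15 with 1 library left out (7 without male RT/saline replicate 2 and without male cold replicate 3). For 2-DG against cold 1 gene became 4 by DESeq2, 2 with male mice summed, 0 with the term for pooled libraries, and 0 to 3 with 1 library left out, 2 without male RT/saline replicate 1, 2 without replicate 3, 0 without female cold, 0 without male 2-DG and 3 without female 2-DG. Between sexes 41 genes became 3 with male mice summed, 2 with the term for pooled libraries, and 2 to 45 with 1 library left out, 2 without female RT/saline, 17 without female cold, 23 without male 2-DG and 26 without female 2-DG. The share of cells with Fos differed by 10.95 percentage points, 9.84 to 13.2 with 1 library left out and 3.18 over the marker gate (exact two-sided permutation p = 0.2). The SPN-like share differed by -0.0138 percentage points and reversed to 0.0166 without male cold replicate 3, in a range of -0.0307 to 0.0166. Subclusters with a Fos rise numbered 4 to 5 under each of 3 alternatives for both treatments, and leaving out 1 library was not run on them.

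Pairing of the male mice by replicate number was not seen, though so few pairs cannot exclude it. Deviations of same-numbered libraries correlated across genes, which are not independent replicates, at -0.07, 0.07 and 0.05 in SPN-like cells and at -0.40, 0.00 and 0.08 over all cells, with the best match at the own number in 1 and 0 pairs. With the replicate block the count was 7 in SPN-like cells and 7 over all cells, within 1.5-fold of the counts without it. Slide as a block was not run, since barcode recurrence did not show which libraries shared a slide.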

Other observations

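The splits of the libraries were planned before the data were examined, and the count over splits that keep sex balanced was chosen after the results had been seen.

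For male cold against RT/saline, the 10 splits of the 6 libraries are too few for a share under 0.05. In SPN-like cells the real split called 6 genes and the highest other 0, over all cells 10 and 0, and over the other classes 54 and 14, so that in each case 1 split, the real one, gave as many. For cold in both sexes, 1 of 35 splits was as large in SPN-like cells (7 genes, highest other 0) and over all cells (11 genes, highest other 0), which excludes chance at 0.05 only if splits that put both female libraries on 1 side are counted. The 20 splits with 1 female library on each side are too few for a share under 0.05, with 7 genes against a highest other of 0 in SPN-like cells and 11 against 0 over all cells. For female against male in SPN-like cells 1 of 100 drawn splits was as large (41 genes, highest other 4). This excludes chance only for splits that ignore treatment and pooling, since neither was held fixed, and sex and pooling overlap.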
